A study of Homo sapiens with 4 samples.

How the data were processed

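Total RNA of H1299 cells was sequenced from 4 libraries, 2 wild type and 2 with TTC28 targeted by CRISPR/Cas9, prepared with an Illumina TruSeq RNA kit per the labels. Reads were aligned with HISAT2 2.0.5 to hg38, per the submitters' processing notes. The read counter, its strand setting and the annotation release are not given in the sources used here. All values come from a single deposited table with 58735 genes, 30992 of them with a count in at least 1 library.

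The deposited table holds a raw count per gene and library, whole numbers with different sums per library, per the file headers. The authors also deposited FPKM values, made from these counts, the gene length in the table and an effective size per library that lay between 0.965 and 1.02 of the total count. The deposited columns of each group's mean normalized signal, taken from scaled counts by the authors per the file headers, were not used for any test. The authors' deposited log2 fold change, knockout over wild type, and their deposited p-value and adjusted p-value come from a test whose tool the headers do not name, and were compared with the values computed here. No column of a sample was left unused in the comparison.

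Libraries were assigned to groups and replicate numbers from the labels. The library totals ranged from 25120500 to 28885443 counts. Gene identities, types and coordinates are those of the table. All its gene identifiers are in GENCODE release 29, and 99.92% have identical coordinates there, which gave exon overlaps. GC content was that of each gene's longest transcript in the same release, for 99.93% of the tested genes. Spreadsheet software had turned 27 symbols into dates, which were restored from a table of 58207 gene identifiers and names.

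Genes with at least 1 FPKM in at least 2 libraries were tested. The plan was limma on log2 FPKM, with edgeR's quasi-likelihood test to replace it if the table held raw counts; since it did, the counts were tested with edgeR 4.0.16 under R 4.3.3, with TMM factors (0.978 to 1.02), no covariates and a two-sided test. P-values were adjusted by the Benjamini-Hochberg method over the 13079 tested genes, with a threshold of 0.05, and changes of at least 2-fold required a log2 fold change of at least 1 in size. Standard errors of fold changes come from the same fit, with a median of 0.0886, and the common biological coefficient of variation was 0.0566. An exact permutation of 2 against 2 libraries cannot give p under 0.333, so that no test of a single gene by permutation was made. Ratios of genes with few counts in a group were taken from summed counts, scaled by effective library sizes, with 95% exact Clopper-Pearson intervals, and no ratio is given where a group had 0 counts.

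The genes named were set by a rule: TTC28, the 12 genes with the largest rise and the 12 with the largest fall among protein-coding genes past the threshold, with a mean of at least 5 FPKM in the higher group and the same direction in every pairing of a knockout with a wild-type library (4160 genes, 1937 higher and 2223 lower, qualified), and for each list up to 4 members with the smallest p, of which some are left out of the text. The text also names ICAM1, IRF7, ATF4, MT-RNR1, ENG and EGFL7, which were chosen after their values were seen. The 42 gene lists hold 1009 entries, of which 1008 were found in the table. Lists with at least 5 tested members (38) were compared with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry, and adjusted over the 38 lists. The design, the lists, the rule for named genes and the settings named next as planned were fixed before the data were examined.

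The settings planned were filters of at least 0.1 or 5 FPKM or none, median-of-ratios scaling, protein-coding genes only, limma on log2 FPKM with pseudocounts of 1, 0.5 or 0.1, and, within limma, quantile normalization, a TPM scale, no trend and robust shrinkage. Also planned were leaving out each library in turn, where the lone library of a group is assumed to vary like the others, and a replicate block. The median-of-ratios factors had been planned from FPKM and were computed from counts. Alternatives chosen after seeing the data were DESeq2 1.42.0, total-count scaling, the sizes behind the authors' FPKM, totals without mitochondrial genes, filterByExpr, robust shrinkage in edgeR, removal of the local median of 25 neighbouring genes on each side, and removal of a trend on GC content and length. Chromosomes and windows of 10 Mb with at least 20 tested genes were compared by median log2 fold change, with 10000 permutations of gene positions, also after seeing the data.

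EdgeR, limma, DESeq2, camera and the removal of the local median were tested on simulated data drawn from the means and sizes of these libraries. Removal of the GC and length trend, fry, the exact intervals and the permutation of gene positions were not tested on simulated data. For knockout against wild type over 13079 genes, 68, 66 and 66 genes were changed by 0.5, 1 and 2 on the log2 scale. Of these edgeR recovered 73.5%, 89.4% and 98.5%, with 8 false calls. So few changed genes, drawn independently, cannot show how the calls behave in these data, where 50.3% of the tested genes changed. Removal of the local median took a simulated shift of chromosome 21 from -0.37 to 0.0031. Figures and summaries were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.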

Results

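RNA sequencing measured gene expression in H1299, a human non-small cell lung cancer line that lacks functional p53. The series holds 4 libraries, 2 of wild-type cells and 2 of cells in which TTC28 had been targeted with CRISPR/Cas9. Wild-type replicates 1 and 2 held 25808423 and 27043491 counts over 58735 genes, and knockout replicates 1 and 2 held 28885443 and 25120500. A gene was tested where it had at least 1 FPKM (fragments per kilobase of gene length, scaled to library size) in at least 2 of the 4 libraries, which left 13079 genes, 10795 of them protein coding. The log CPM of the libraries had a Pearson correlation across genes of 0.995 within wild type, 0.994 within the knockout and 0.969 to 0.972 between the groups (genes are not independent replicates). Mitochondrially encoded genes took 6.07% of the counts in wild-type replicate 1 (95% Wilson interval 6.06 to 6.08), 5.87% in wild-type replicate 2 (5.86 to 5.88), 8.61% in knockout replicate 1 (8.60 to 8.62) and 10.16% in knockout replicate 2 (10.15 to 10.18). Intervals on counts cover counting error only. P-values of single genes measure only the spread between these libraries, since the labels do not say that replicates came from separate cultures or clones. The p-values of camera and of the permutation of gene positions compare genes with other genes, and measure no spread between cultures.

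TTC28 itself (ENSG00000100154, hg38 chromosome 22, 27978014 to 28679865, minus strand) encodes a large protein with tetratricopeptide repeats. Its transcript was lower in both knockout libraries but still present, at 4.88 and 5.44 FPKM in wild-type replicates 1 and 2 against 2.96 and 2.99 FPKM in knockout replicates 1 and 2. The counts behind these values were 1617, 1875, 1042 and 924, and the group means were 5.16 ± 0.398 FPKM (SD, n = 2) in wild type and 2.97 ± 0.0249 FPKM (SD, n = 2) in knockout libraries. TTC28 fell by 0.79 on the log2 scale (SE 0.0764), to 0.577 of wild type, lower in 2 of 2 knockout libraries (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 2.78e-06). A count over the whole gene does not examine the edited part or the protein. The gene TTC28-AS1 on the opposite strand shares 933 exonic bases with TTC28 (7.38%) and had 243, 258, 412 and 359 counts in the same order. The strand setting of the counting is not given in the sources used here, so reads of the shared part cannot be assigned.

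The comparison of wild-type and knockout cells asks which transcripts differ when TTC28 has been targeted. Expression differed widely but mostly by small amounts: 6581 of the 13079 tested genes (50.3%) changed, 3281 higher and 3300 lower in the knockout, and 3747 of the 6581 (56.9%) by less than 0.5 on the log2 scale. Changes of at least 2-fold were found for 681 genes, 386 higher and 295 lower, and changes of at least 4-fold for 64 genes that rose and 55 that fell. Calls rest on edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. The values of the groups did not overlap for 75.5% of the tested genes, where chance gives 33.3%. On a TPM scale, where each library's FPKM values are scaled to the same sum, only 25.5% of 6199 called genes were higher, against 49.9% here, and the median of all tested genes shifted by -0.16.

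Among protein-coding genes with a mean of at least 5 FPKM in the higher group, the largest rises included GPER1, ALCAM, NOTCH3 and ITGB4. GPER1 encodes the G protein-coupled estrogen receptor. GPER1 (ENSG00000164850, chromosome 7, 1082208 to 1093815) was at 1.25 ± 0.0834 FPKM (SD, n = 2) in wild type and 8.61 ± 0.0644 FPKM (SD, n = 2) in knockout libraries, 6.91-fold higher, and ALCAM, a cell adhesion molecule, was 5.72-fold higher. NOTCH3, a Notch receptor, was 4.46-fold higher, at 1.68 ± 0.0439 FPKM (SD, n = 2) in wild type and 7.50 ± 0.107 FPKM (SD, n = 2) in knockout libraries. ITGB4 (ENSG00000132470, chromosome 17, 75721328 to 75757818), the integrin beta subunit of hemidesmosomes, was at 10.2 ± 0.530 FPKM (SD, n = 2) in wild type and 38.4 ± 1.65 FPKM (SD, n = 2) in knockout libraries, and JUP, which encodes plakoglobin of desmosomes and adherens junctions, was 3.70-fold higher. The other genes of this group, with log2 fold changes ± SE, were the aminopeptidase gene LVRN (2.27 ± 0.0813), the extracellular matrix gene ECM1 (2.05 ± 0.128), the zinc finger gene SALL3 (1.94 ± 0.0786), FSTL1 (1.89 ± 0.0801), SEL1L3 (1.81 ± 0.0980) and the N-glycan branching enzyme gene MGAT5 (1.70 ± 0.0729). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 2.02e-09 for GPER1, 8.78e-10 for ALCAM, 8.78e-10 for NOTCH3 and 7.67e-10 for ITGB4, each higher in 2 of 2 knockout libraries. EIF3CL (2.32 ± 0.363) met the same rule but is uncertain: its near-identical copy EIF3C can share its reads, and its counts of 160, 178, 1312 and 379 put most of the rise in knockout replicate 1. EIF3C had 1388, 1083, 1969 and 511 counts, and the EIF3CL adjusted p was 0.163 in edgeR's quasi-likelihood test with robust shrinkage and Benjamini-Hochberg adjustment (2.08e-82 to 0.163 over its alternatives).

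Among protein-coding genes with a mean of at least 5 FPKM in the higher group, the largest falls included PPP1R14A, S100A16, SERPINE2 and THBS1. PPP1R14A (ENSG00000167641, chromosome 19, 38251237 to 38256591), which encodes an inhibitor of myosin phosphatase, went from 1167 counts in the wild-type libraries to 4 in the knockout libraries, a ratio of 285 after scaling (95% exact Clopper-Pearson interval 111 to 1050). THBS1 (ENSG00000137801, chromosome 15, 39581079 to 39599466), the matrix protein thrombospondin, was at 11.4 ± 1.07 FPKM (SD, n = 2) in wild type and 1.56 ± 0.0980 FPKM (SD, n = 2) in knockout libraries, 7.29-fold lower. SERPINE2, a secreted protease inhibitor, was 7.53-fold lower, IGFBP4, an insulin-like growth factor binding protein, 5.86-fold lower, and DKK1, a secreted Wnt antagonist, 5.08-fold lower. S100A16, a calcium-binding protein gene, was 11.5-fold lower, at 8.72 ± 0.243 FPKM (SD, n = 2) in wild type and 0.750 ± 0.0732 FPKM (SD, n = 2) in knockout libraries. The other genes of this group, with log2 fold changes ± SE, were the actin regulator gene RFLNA (-2.22 ± 0.109), LURAP1L (-2.07 ± 0.170), the lipolysis inhibitor gene G0S2 (-1.89 ± 0.108), ARHGAP29 (-1.85 ± 0.0909) and the uridine phosphorylase gene UPP1 (-1.83 ± 0.0651). RFPL4A went from 288 to 4 counts, a ratio of 70.3 (27.2 to 260), and is uncertain because of its paralog RFPL4AL1, although the summed counts were 165, 163, 2 and 3. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 3.70e-10 for PPP1R14A, 3.70e-10 for THBS1, 7.67e-10 for SERPINE2 and 4.91e-09 for S100A16, each lower in 2 of 2 knockout libraries. RFLNA shares 7.78% of its exonic bases with ZNF664 on the same strand, and DKK1, THBS1 and FSTL1 share 9.61%, 4.89% and 3.62% of theirs with PRKG1-AS1, FSIP1 and AC063952.1 on the opposite strand.

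**Figure D1:**
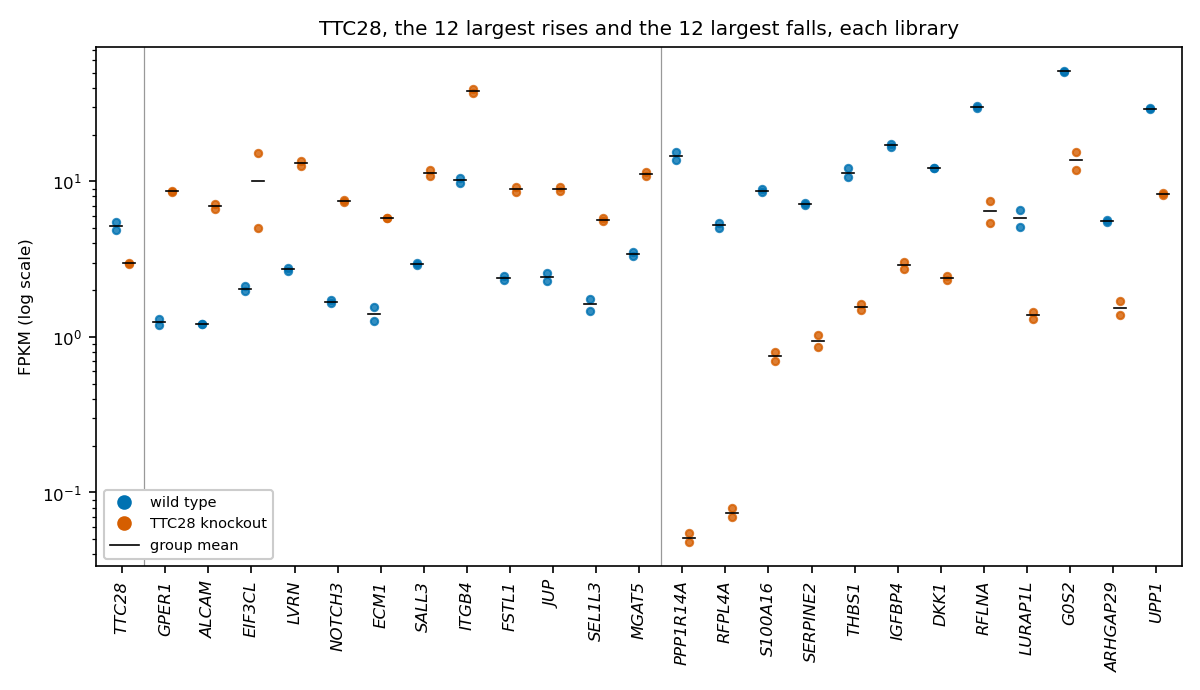
FPKM on a log axis for TTC28 and 24 genes named by the rule, with a point per library and a bar at the mean of each group (n = 2). These genes are the 12 largest rises and 12 largest falls among protein-coding genes with a mean of at least 5 FPKM in the higher group. TTC28 is at 4.88 and 5.44 FPKM in wild type and 2.96 and 2.99 FPKM in the knockout, and the point of EIF3CL in knockout replicate 1 lies far above that of replicate 2.

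Transcript levels also shifted together along parts of chromosomes. In the first 10 Mb of chromosome 5, 100% of the 28 tested genes were lower in the knockout, with a median log2 fold change of -0.82. The median was -0.57 over the 22 tested genes in the first 10 Mb of chromosome 2 and -0.77 over the 24 tested genes from 10 to 20 Mb, while windows tested from 90 to 210 Mb of that chromosome, with the 140 to 150 Mb window too sparse to test, had medians from 0.20 to 0.55. On chromosome 12 the medians ran from -0.45 to -0.30 in the windows from 0 to 40 Mb and from 0.22 to 0.33 from 40 to 70 Mb. Chromosome 21 as a whole had a median of -0.40 over 124 tested genes, of which 4 rose, 70 fell and 83.1% had a negative log2 fold change. Medians were also below 0 on chromosomes 14 (-0.18), 7 (-0.16) and 16 (-0.13) and above 0 on chromosomes 13 (0.19) and 10 (0.11). Of 237 windows of 10 Mb with at least 20 tested genes, 62 had a median beyond 0.2 in size, 29 above and 33 below 0, against 0 between the knockout libraries and 0 between the wild-type libraries. For each of these 6 chromosomes, picked by a median over 0.1 in size, a permutation of gene positions gave p = 1e-04, the smallest that 10000 permutations can give (Benjamini-Hochberg adjusted p = 0.000329 over 23 chromosomes), although genes are not independent replicates. With smaller medians, chromosomes 2 (0.08, adjusted p = 0.000329), 19 (0.06, adjusted p = 0.000575), 5 (-0.05) and 11 (0.05, both at adjusted p = 0.0218) passed the same permutation test. The window of chromosome 22 with TTC28 (20 to 30 Mb) had a median of 0.08 over 90 tested genes. The windows were chosen after seeing the data, as was a second fit with the median of the 25 neighbouring genes on each side removed from each gene, called the local median below.

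**Figure D2:**
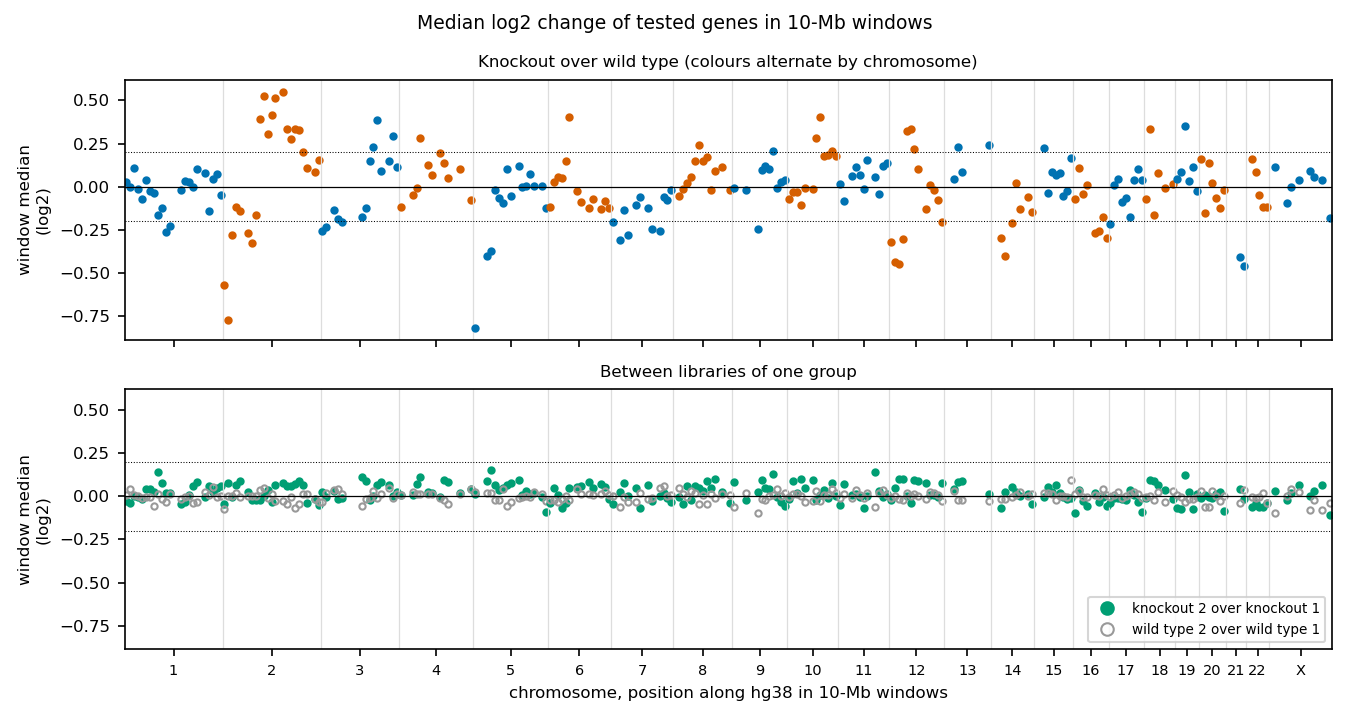
Median log2 fold change, knockout over wild type, of the tested genes in 10 Mb windows with at least 20 tested genes along each chromosome of hg38, beside the same medians between the libraries of one group. In the comparison of the groups 62 of 237 windows lie beyond 0.2 in size, with chromosome 5 from 0 to 10 Mb at -0.82, and 0 do so between libraries of one group.

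Genes of lipid synthesis were higher in the knockout. Of 22 tested cholesterol synthesis genes, 18 rose, 1 fell and 3 did not pass, among them the sterol sensor INSIG1 (1.09 ± 0.0606) and the sterol transporter gene STARD4 (1.35 ± 0.0832). Of 18 tested genes of fatty acid synthesis and desaturation, 16 rose, 1 fell and 1 did not pass, with the desaturase SCD at 583 ± 28.3 FPKM (SD, n = 2) in wild type and 1363 ± 31.6 FPKM (SD, n = 2) in knockout libraries. SREBF1, a master transcription factor of lipid synthesis, was 2.02-fold higher, SCD5 2.38-fold and the acetyl-CoA synthetase gene ACSS2 1.70-fold. Both lists had the same counts adjusted over the list alone. The median log2 fold changes were 0.55 and 0.42. Camera, which compares a list with all other tested genes at a preset correlation of 0.01, gave Benjamini-Hochberg adjusted p-values over 38 lists of 1.99e-10 and 4.90e-09. With an estimated correlation they were adjusted p = 0.255 and adjusted p = 0.352.

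Interferon-stimulated genes were higher and cytokine and NF-kB target genes lower in the knockout. Of 20 tested interferon-stimulated genes, 19 rose, 0 fell and 1 did not pass, IRF7 at a log2 fold change of -0.19. IFIT1 was 4.56-fold higher, at 0.952 ± 0.164 FPKM (SD, n = 2) in wild type and 4.33 ± 0.0338 FPKM (SD, n = 2) in knockout libraries, and IFIT3 (1.46 ± 0.116), IFIT2 (1.45 ± 0.120) and IFI6 (1.10 ± 0.0962) also rose, the examples being those with the smallest p. Of 13 tested NF-kB target, cytokine and chemokine genes, 1 rose, 12 fell and 0 did not pass. The cytokine gene LIF was 4.51-fold lower, at 3.48 ± 0.0155 FPKM (SD, n = 2) in wild type and 0.767 ± 0.0784 FPKM (SD, n = 2) in knockout libraries, and BIRC3 (-1.06 ± 0.0926) and the NF-kB subunit genes RELB (-0.76 ± 0.0709) and NFKB2 (-0.66 ± 0.0681) fell, while the adhesion molecule gene ICAM1 rose. Of 18 tested genes of MHC class I antigen presentation, 12 rose, 1 fell and 5 did not pass, with CALR (0.75 ± 0.0666), B2M (0.52 ± 0.0606), HLA-C (0.57 ± 0.0692) and TAPBP (0.45 ± 0.0649) among those that rose. HLA class I genes resemble one another, so that reads can be shared between them. Adjusted over the list alone, the counts of these lists were the same. The camera adjusted p-values (Benjamini-Hochberg) were 4.90e-09, 5.70e-06 and 0.00484, at medians of 0.65, -0.76 and 0.33. With an estimated correlation they were adjusted p = 0.255, adjusted p = 0.269 and adjusted p = 0.352. Of 11 tested immune checkpoint and stress ligand genes, 4 rose, 2 fell and 5 did not pass, the same adjusted over the list alone, with MICB (0.68 ± 0.0645), NECTIN2 (0.44 ± 0.0615) and VSIR (1.19 ± 0.125) higher and ULBP1 (-0.69 ± 0.101) lower (camera adjusted p = 0.258).

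Targets of MYC and of ATF4 were lower in the knockout. MYC, the transcription factor of growth, was 2.39-fold lower, at 110 ± 2.78 FPKM (SD, n = 2) in wild type and 46.0 ± 2.24 FPKM (SD, n = 2) in knockout libraries. Of 25 tested MYC target genes, 1 rose, 21 fell and 3 did not pass, among them the polyamine synthesis genes ODC1 (-1.74 ± 0.0660) and SRM (-1.01 ± 0.0633) and the ribosome biogenesis genes RRP9 (-1.35 ± 0.0793) and MYBBP1A (-0.91 ± 0.0656). Of 26 tested targets of ATF4, the transcription factor of the integrated stress response, 1 rose, 21 fell and 4 did not pass (1 and 22 past adjusted over the list alone). SESN2 (1.99-fold lower), TRIB3 (-0.92 ± 0.0624), the serine synthesis gene PSPH (-0.98 ± 0.0712) and CEBPB (-0.84 ± 0.0623) were among those that fell, and ATF4 itself was at -0.02. The MYC target list kept its counts adjusted over the list alone. The medians were -0.60 and -0.58, with camera adjusted p-values (Benjamini-Hochberg) of 2.64e-14 and 3.17e-10. With an estimated correlation they were adjusted p = 0.255 and adjusted p = 0.255.

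Mitochondrially encoded transcripts were higher in the knockout, and nuclear genes of the respiratory chain went both ways. Of 15 tested mitochondrially encoded genes, 14 rose, 0 fell and 1 did not pass (15 and 0 past adjusted over the list alone), and MT-CO3 was at 7277 ± 262 FPKM (SD, n = 2) in wild type and 13392 ± 1439 FPKM (SD, n = 2) in knockout libraries. MT-ND3 (0.89 ± 0.0716), MT-ATP6 (0.85 ± 0.0913) and MT-CO2 (0.81 ± 0.0944) rose, and the ribosomal RNA gene MT-RNR1 was at 0.15, not past the threshold. The median was 0.745 and the camera adjusted p (Benjamini-Hochberg) 5.23e-09, with adjusted p = 0.571 with an estimated correlation. The list did not pass fry (adjusted p = 0.063). Under quantile normalization, which sets genes of equal rank to equal values, the median of the list, MT-CO2, MT-CO3 and MT-ATP6 came to 0 by construction. Of 32 tested nuclear genes of the respiratory chain, 12 rose, 6 fell and 14 did not pass, the same adjusted over the list alone (camera adjusted p = 0.689), with COX7B (0.56 ± 0.0666), ATP5MC3 (0.61 ± 0.0745) and NDUFS1 (0.42 ± 0.0635) higher. SDHA was at -0.45 ± 0.0714, but lies in the first 10 Mb of chromosome 5 and came to 0.39 with the local median removed. Of 20 tested glycolysis genes, 5 rose, 9 fell and 6 did not pass, the same adjusted over the list alone (camera adjusted p = 0.71), with SLC16A3 (0.84 ± 0.0803) and PFKM (0.69 ± 0.0671) higher and TPI1 (-0.51 ± 0.0790) and PFKL (-0.54 ± 0.0703) lower. PFKL, on chromosome 21, did not pass with the local median removed.

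Genes of cell division, the process in which TTC28 has been described, changed in both directions, with more falls than rises among genes of mitosis and G2/M. Of 22 tested genes of the central spindle and cytokinesis, 4 rose, 5 fell and 13 did not pass (4 and 3 past adjusted over the list alone), with SEPTIN9 (0.66 ± 0.0654) and ANLN (0.41 ± 0.0612) higher and the chromosomal passenger genes BIRC5 (-0.43 ± 0.0683) and CDCA8 (-0.36 ± 0.0616) lower. Of 25 tested genes of mitosis and G2/M, 3 rose, 12 fell and 10 did not pass, with the same counts adjusted over the list alone. The ubiquitin-conjugating enzyme gene UBE2C was 1.93-fold lower, at 144 ± 3.83 FPKM (SD, n = 2) in wild type and 74.5 ± 0.655 FPKM (SD, n = 2) in knockout libraries, CENPA (-0.69 ± 0.0754) fell, and CDC25B (0.62 ± 0.0605) and BUB1 (0.55 ± 0.0646) rose. Of 25 tested genes of DNA replication and G1/S, 7 rose, 8 fell and 10 did not pass (7 and 9 past adjusted over the list alone), with RRM2 (-0.80 ± 0.0709) and CDC25A (-0.62 ± 0.0875) lower and MCM6 (0.55 ± 0.0635) and MCM3 (0.41 ± 0.0596) higher. BUB1, RRM2 and MCM6, all on chromosome 2, did not pass with the local median removed. Camera adjusted p-values (Benjamini-Hochberg) were 0.802, 0.141 and 0.747. The mitosis and G2/M list passed as lower with at least 0.1 FPKM (camera adjusted p = 0.0285), with no filter (0.00791) and on the TPM scale (0.0264), at 0.00791 to 0.432 over its alternatives at the preset correlation. Replication-dependent histone genes, whose transcripts peak in S phase, were lower: of 13 tested, 0 rose, 7 fell and 6 did not pass, the same adjusted over the list alone, with HIST1H2BD (-0.75 ± 0.108), HIST1H2AC (-0.50 ± 0.0735) and HIST1H2AG (-0.55 ± 0.0966) as examples (median -0.47). Their camera adjusted p (Benjamini-Hochberg) was 0.0413, with adjusted p = 0.471 with an estimated correlation. It was 0.0583 without wild-type replicate 2, 0.0596 without knockout replicate 1 and 0.0703 without knockout replicate 2 (0.000286 to 0.215 over its alternatives at the preset correlation), and histone genes resemble one another.

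Targets of p53 and apoptosis regulators moved both ways. Of 20 tested p53 target genes, 5 rose, 5 fell and 10 did not pass, with TP53INP1 (1.32 ± 0.0825) higher and SESN2, GADD45A (-0.96 ± 0.0707) and AEN (-1.08 ± 0.0978) lower. Of 21 tested apoptosis regulators, 8 rose, 4 fell and 9 did not pass. The proapoptotic genes BMF (2.18-fold higher) and BCL2L11 (1.08 ± 0.103) rose, and CYCS, which encodes cytochrome c (-1.15 ± 0.0665), and BIRC3, an inhibitor of apoptosis, fell. Both lists had the same counts adjusted over the list alone, and camera adjusted p-values (Benjamini-Hochberg) were 0.485 and 0.732.

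Genes of cell identity shifted in several directions. Of 10 tested neuroendocrine and neuronal genes, 1 rose, 6 fell and 3 did not pass (1 and 7 past adjusted over the list alone), with a median of -0.44. NEFH, a neurofilament gene near TTC28 on chromosome 22, went from 582 to 6 counts, a ratio of 94.7 (95% interval 43.3 to 259), and SNAP25 of synaptic vesicle fusion (-4.08 ± 0.206), CHGB (-1.38 ± 0.0973) and INA (-0.46 ± 0.0612) fell. The camera adjusted p (Benjamini-Hochberg) was 8.49e-05, with adjusted p = 0.294 with an estimated correlation, and 0.283 over the members with at least 5 FPKM in 2 libraries (1.5e-05 to 0.283 over its alternatives at the preset correlation). Of 9 tested epithelial genes, 6 rose, 2 fell and 1 did not pass, with KRT8 (0.74 ± 0.0657) and TJP3 (1.07 ± 0.148) higher and CLDN1 (-1.37 ± 0.0632) and KRT7 (-1.58 ± 0.175) lower. Of 18 tested mesenchymal genes, 8 rose, 6 fell and 4 did not pass, with a median of 0.12 but a mean of -0.36. The matrix gene TNC went from 641 to 5 counts, a ratio of 125 (53.4 to 387), FN1 (-1.34 ± 0.0895) and TGFBI (-1.36 ± 0.0872) fell and LOXL2 (0.83 ± 0.0611) rose. Of 16 tested genes of the extracellular matrix and integrins, 8 rose, 5 fell and 3 did not pass (9 and 6 past adjusted over the list alone). ITGA5 (1.13 ± 0.0649) and ITGA6 (0.72 ± 0.0664) were higher beside ITGB4, and THBS1 (-2.87 ± 0.0892) was lower. Of 5 tested lung lineage genes, 4 rose, 1 fell and 0 did not pass, with GATA6 2.93-fold lower, AGER (0.71 ± 0.140) and LAMP3 (0.52 ± 0.114) higher, and ABCA3 (0.20 ± 0.0616) not past without wild-type replicate 1 (adjusted p = 0.181 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0.00323 to 0.714 over its alternatives). Of 8 tested stemness genes, 2 rose, 3 fell and 3 did not pass. SOX9 (-1.16 ± 0.0729) and KLF4 (-0.49 ± 0.0725) were lower beside MYC, and ITGA6, also on this list, was higher. Of 11 tested cancer testis antigen genes, 1 rose, 6 fell and 4 did not pass, with PRAME 1.89-fold higher and MAGEA3 (-0.41 ± 0.0719), MAGEA12 (-0.36 ± 0.0731) and MAGEA6 (-0.31 ± 0.0665), which resemble one another, lower. The epithelial, mesenchymal, lung, stemness and cancer testis lists had the same counts adjusted over the list alone, and camera adjusted p-values (Benjamini-Hochberg) were 0.689 for epithelial, 0.479 for mesenchymal, 0.393 for matrix and integrin, 0.946 for lung lineage, 0.166 for stemness and 0.464 for cancer testis antigen genes. The stemness list passed as lower with at least 0.1 FPKM (camera adjusted p = 0.0495), with filterByExpr (0.0265) and, at a median of 0.02, with the local median removed (0.0206), at 0.0206 to 0.76 over its alternatives at the preset correlation.

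At the filter of 1 FPKM the Wnt target list passed camera as lower, while the Notch, TGF-beta, YAP and TEAD, ERK and PI3K lists did not pass. Of 9 tested Wnt target genes, 2 rose, 4 fell and 3 did not pass, with DKK1, MYC, NKD2 (-1.04 ± 0.176) and CCND1 (-0.38 ± 0.0669) lower, at a median of -0.30. The camera adjusted p (Benjamini-Hochberg) was 0.0107, with adjusted p = 0.604 with an estimated correlation. It was 0.328 with limma on log2 FPKM (0.00238 to 0.484 over its alternatives at the preset correlation). The Wnt median turned positive, and the call ended, with at least 0.1 FPKM (0.05), with no filter (0.06) and with filterByExpr (0.06). NKD2, in the first 10 Mb of chromosome 5, did not pass with the local median removed. Of 15 tested Notch pathway genes, 5 rose, 6 fell and 4 did not pass, with NOTCH3 higher and JAG1 (-1.26 ± 0.0934), HES1 (-1.35 ± 0.130) and HES4 (-0.93 ± 0.0852) lower. Of 19 tested TGF-beta target genes, 3 rose, 6 fell and 10 did not pass, with PMEPA1 8.94-fold lower, TGIF1 (9.45 FPKM in wild type and 4.72 FPKM in the knockout) and ANGPTL4 (-0.90 ± 0.0929) also lower. Of 20 tested YAP and TEAD target genes, 9 rose, 4 fell and 7 did not pass (9 and 5 past adjusted over the list alone), with ANKRD1 (1.53 ± 0.115) and ARHGEF17 (0.59 ± 0.0626) higher and AJUBA (-0.75 ± 0.0693) and DLC1 (-0.71 ± 0.0616) lower. Of 21 tested genes of ERK pathway output, 6 rose, 9 fell and 6 did not pass, with EGR1 2.41-fold higher and FOSL1 (-0.76 ± 0.0622) and PHLDA1 (-0.64 ± 0.0636) lower. Of 23 tested genes of PI3K, AKT and FOXO, 15 rose, 4 fell and 4 did not pass, with PIK3IP1 (1.81 ± 0.152) and IGF1R (0.80 ± 0.0846) higher and SGK1 (-0.99 ± 0.0816) lower. The Wnt, Notch, TGF-beta, ERK and PI3K lists had the same counts adjusted over the list alone. Camera adjusted p-values (Benjamini-Hochberg) were 0.946 for Notch, 0.258 for TGF-beta, 0.802 for YAP and TEAD, 0.386 for ERK and 0.159 for PI3K, AKT and FOXO. The last list passed as higher with at least 0.1 FPKM (camera adjusted p = 0.0285), with no filter (0.0123) and on the TPM scale (0.0483), at 0.0123 to 0.764 over its alternatives at the preset correlation. The Notch list had a median of 0.01 and a mean of -0.02.

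Heat shock genes were higher in the knockout, while the endoplasmic reticulum, NRF2, hypoxia, autophagy and ribosomal protein lists did not pass camera at the filter of 1 FPKM. Of 15 tested heat shock genes, 7 rose, 1 fell and 7 did not pass, with the same counts adjusted over the list alone. The cochaperone gene BAG3 was 1.92-fold higher, at 23.1 ± 0.0109 FPKM (SD, n = 2) in wild type and 44.2 ± 0.817 FPKM (SD, n = 2) in knockout libraries, and HSPB1 (0.92 ± 0.0642), HSPA8 (0.62 ± 0.0690) and HSPA1B (0.60 ± 0.0972), which has a near-identical copy, rose. The median was 0.23, the camera adjusted p (Benjamini-Hochberg) 0.00525, and adjusted p = 0.471 with an estimated correlation. With the local median removed it was adjusted p = 0.0633 (0.000282 to 0.0633 over its alternatives at the preset correlation). Of 20 tested genes of endoplasmic reticulum chaperones and XBP1 targets, 8 rose, 3 fell and 9 did not pass, with CALR and EDEM1 (0.67 ± 0.0909) higher and XBP1 (-0.39 ± 0.0620) lower. PDIA6 (-0.54 ± 0.0677), in the window from 10 to 20 Mb of chromosome 2, came to 0.16 with the local median removed. Of 16 tested NRF2 target genes, 2 rose, 6 fell and 8 did not pass, with SLC7A11 (-0.61 ± 0.0668), GCLM (-0.81 ± 0.0934), OSGIN1 (-0.65 ± 0.0954) and TXNRD1 (-0.41 ± 0.0622) lower. Of 16 tested hypoxia target genes, 3 rose, 8 fell and 5 did not pass, with DDIT4 (-0.65 ± 0.0703) and STC2 (-0.55 ± 0.0638) lower and the glucose transporter gene SLC2A1 (0.51 ± 0.0600) higher. Of 28 tested genes of autophagy and the lysosome, 7 rose, 10 fell and 11 did not pass, with MITF 5.80-fold higher and MAP1LC3B (-0.95 ± 0.0641), SQSTM1 (-0.44 ± 0.0705) and ATG5 (-0.46 ± 0.0713) lower, at a median just below 0 and a mean of 0.03. Of 40 tested ribosomal protein genes, 0 rose, 11 fell and 29 did not pass (0 and 8 past adjusted over the list alone), with RPL37 (-0.74 ± 0.101) and RPL32 (-0.41 ± 0.0769) as examples. RPL14 and RPL5 also fell, but did not pass with the local median removed, and the list passed as lower without wild-type replicate 2 (camera adjusted p = 0.032), without knockout replicate 1 (0.00329), with at least 0.1 FPKM (0.0271), with no filter (0.00517) and on the TPM scale (0.0254; 0.00329 to 0.598 over its alternatives at the preset correlation). Camera adjusted p-values (Benjamini-Hochberg) were 0.479 for endoplasmic reticulum, 0.258 for NRF2, 0.0997 for hypoxia, 0.773 for autophagy and 0.161 for ribosomal protein genes. The hypoxia list passed as lower with at least 0.1 FPKM (camera adjusted p = 0.0129), with no filter (0.0118) and with filterByExpr (0.0265), at 0.0118 to 0.283 over its alternatives at the preset correlation. The endoplasmic reticulum, NRF2, hypoxia and autophagy lists had the same counts adjusted over the list alone. Both tested metallothionein genes fell, MT1X (-0.55 ± 0.127) and MT2A (-0.28 ± 0.0797), the same adjusted over the list alone, but neither passed with the local median removed, nor did MT2A without wild-type replicate 1 (adjusted p = 0.187 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5.66e-05 to 0.938 over its alternatives).

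Around the target, 18 neighbours of TTC28 on chromosome 22 were tested, of which 6 rose, 5 fell and 7 did not pass. Besides NEFH, NF2 (-0.77 ± 0.0770) fell, and NIPSNAP1 (0.52 ± 0.0640) and CHEK2 (0.62 ± 0.0845), the gene beside TTC28, rose. Of 24 other tested genes of the TTC series, 5 rose, 5 fell and 14 did not pass, with TTC14 (1.04 ± 0.0938) and TTC21B (0.60 ± 0.0729) higher and TTC27 (-0.71 ± 0.0852) lower. TTC30A (0.69 ± 0.157) resembles TTC30B and did not pass with the local median removed, nor in limma at a pseudocount of 0.1, with quantile normalization or on the TPM scale (Benjamini-Hochberg adjusted p of 0.000292 to 0.0986 over its alternatives in edgeR, limma and DESeq2). Both lists had the same counts adjusted over the list alone, with camera adjusted p-values (Benjamini-Hochberg) of 0.464 and 0.748. Few markers of other cell types reached the level for testing, namely 0 of 22 blood cell markers, 1 of 18 fibroblast and smooth muscle markers and 2 of 16 endothelial markers. FBLN1 (0.57 ± 0.0764) rose, and the endothelial markers ENG and EGFL7 were at 0.14 and 0.04, not past the threshold, with the same counts adjusted over the list alone.

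Of the 38 lists with at least 5 tested members, 12 passed camera, 6 higher and 6 lower in the knockout. With an estimated correlation 0 lists passed, and 6 were at an unadjusted p under 0.05. Fry, which asks whether the genes of a list move on balance one way, passed 15 lists. These were 11 of the 12, without the mitochondrial list (fry adjusted p = 0.063), and also the TGF-beta, checkpoint ligand, hypoxia and NRF2 lists. In simulated data, camera with an estimated correlation left a list shifted by construction at an adjusted p of 0.163, against 4.43e-69 at the preset correlation. The simulated genes were drawn independently of one another. The simulation therefore cannot decide between the correlations where genes of a list vary together. The estimates lay below 0.01 for the interferon (-0.033), NF-kB (-0.0767), MHC (-0.0225) and ATF4 (-0.0371) lists. They also did for the MYC (0.00673), histone (-0.0626) and neuroendocrine (-0.104) lists. For these lists, a higher correlation is argued against as the reason for the larger p-values. Estimates were above 0.01 for the cholesterol (0.0271), heat shock (0.0549), fatty acid (0.16), Wnt (0.272) and mitochondrial (0.68) lists. None of the 12 lists changed sign under the other scalings, apart from the mitochondrial list at 0 under quantile normalization. The medians of the Notch, TGF-beta, YAP and TEAD, apoptosis, autophagy, endoplasmic reticulum, checkpoint ligand, mesenchymal, respiratory chain and TTC series lists changed sign under at least 1 of them.

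**Figure D3:**
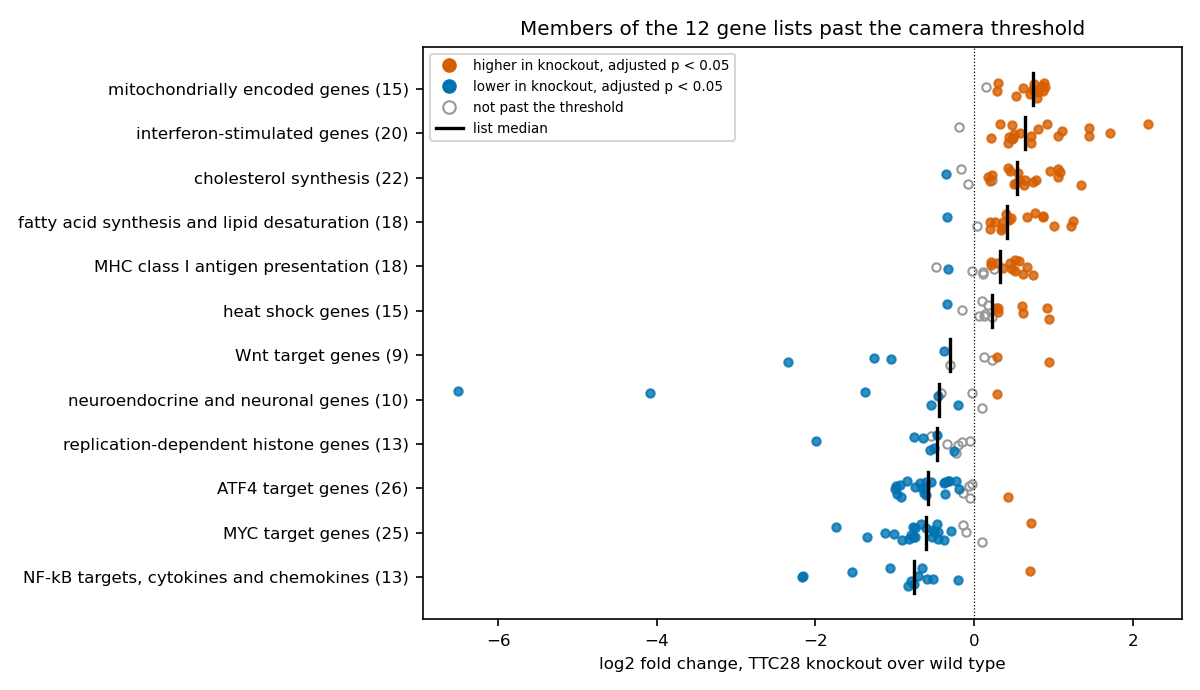
Log2 fold changes, knockout over wild type, of the tested members of the 12 gene lists past camera, with a point per gene, filled where the gene changed, and a line at the median of each list. The medians of the interferon-stimulated and cholesterol synthesis genes lie at 0.65 and 0.55, and those of the MYC and ATF4 target genes at -0.60 and -0.58.

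The deposited table also holds the authors' own comparison, with p-values for 27926 genes. Their adjusted p was under 0.05 for 5754 genes, 2743 higher and 3011 lower in the knockout, and 1084 of these changed by at least 2-fold. Among the 13079 genes tested here, 5136 were called in the authors' table, of which 5123 were also called here in the same direction and 13 were not called, and 1458 were called here alone. The log2 fold changes of both sources had a Pearson correlation of 0.9994 across these genes, which are not independent replicates, and come from the same libraries. TTC28 had a log2 fold change of -0.81 and an adjusted p of 2.36e-13 in the authors' table.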

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

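Tests chosen only after the result was seen were those with DESeq2, total-count scaling, the sizes behind the authors' FPKM, totals without mitochondrial genes, filterByExpr, robust shrinkage in edgeR, and removal of the local median or of the GC and length trend. With all 4 libraries the count of genes changed stayed within 1.5 times of 6581 (5465 to 7972; DESeq2 5537) except with at least 5 FPKM, where 7490 genes were tested and 4346 changed, 2169 higher and 2177 lower. On the TPM scale 6199 changed but only 1582 were higher, and 192 of 580 genes changed by at least 2-fold were higher. The mitochondrial share of summed FPKM, 22.4% and 22.1% in wild type and 30.0% and 34.5% in the knockout, enters that scale.

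The count of genes changed by at least 2-fold depended most on the filter and the pseudocount. It was 1545 (786 higher, 759 lower) with at least 0.1 FPKM, 198 (107 and 91) with at least 5 FPKM, 1760 (869 and 891) with no filter, 1548 (786 and 762) with filterByExpr and 437 (248 and 189) for protein-coding genes only, settings that test other numbers of genes. With limma it was 266 (145 and 121) at a pseudocount of 1, 429 (225 higher) at 0.5 and 657 at 0.1, and at a pseudocount of 1 also 258 (140 and 118) with quantile normalization, 261 (141 and 120) without a trend and 252 (133 and 119) with robust shrinkage. A pseudocount of 1 draws the fold changes of low values toward 0.

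With an estimated correlation 0 gene lists passed, and in the other settings 9 to 17 did. At the preset correlation, 264 of 286 values of the 12 lists under alternatives kept direction and call, and 7 lists did so in all of these. The Wnt target list did not pass with limma, filterByExpr or lower filters. With limma its median stayed negative. With filterByExpr and the lower filters it turned positive over more tested members (0.0532 with at least 0.1 FPKM, camera adjusted p = 0.278). Of 4120 alternative values of the 166 named genes past the threshold, 4087 kept direction and call, 31 did not pass and 2 reversed with the local median removed: SDHA at 0.39 (adjusted p = 0.000591 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; 1.65e-11 to 0.0176 over its alternatives) and PDIA6 at 0.16 (adjusted p = 0.0725; 4.63e-16 to 0.0725). Their neighbouring genes were lower by more than they were. TTC28 fell in all 24 alternatives that test it, from -0.91 to -0.63 (largest adjusted p = 0.00468, Benjamini-Hochberg), and has no value with at least 5 FPKM in 2 libraries, since only 1 reaches it.

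Leaving out each library in turn gave 4854 to 6456 genes changed, 638 to 738 changed by at least 2-fold, 11 to 12 lists and a TTC28 log2 fold change of -0.87 to -0.72. A replicate block gave 7108, 689, 11 lists (histone genes at adjusted p = 0.0586) and -0.79; the numbers do not show that the libraries are paired, since the deviations of same-numbered libraries had a correlation of -0.0014 over 2 pairs. Genes under 1 FPKM in all or all but 1 library enter only the settings with lower filters or none. The cause of other differences between settings was not tested.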

Other observations

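Tests chosen only after the result was seen were the search for genes nearly absent in a group, the share of lower genes on chromosome 21, and the test of scaling for the mitochondrial transcripts. The removals of the local median and of the GC and length trend were chosen after seeing the data, but before the values they are used to test.

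Some genes were expressed in the wild-type libraries and nearly absent from the knockout libraries. Of the genes past the threshold, 15 had a mean of at least 1 FPKM in wild type and under 0.1 FPKM in the knockout, 14 of them protein coding, and 4 showed the opposite, 2 of them protein coding. A further 4 tested genes met the same levels on 3 to 5 counts in all and did not pass. MYO10 (chromosome 5), an unconventional myosin of filopodia, went from 2610 counts in wild type to 8 in the knockout, a ratio of 319 (95% exact interval 161 to 739), and the kinase gene RIPK4 (chromosome 21) from 806 to 9, a ratio of 87.5 (45.8 to 192). The glycosyltransferase gene GALNT14 had 452 counts in wild type and 0 in the knockout, and DPEP3 had 251 and 0, where a count of 0 allows up to 3 counts over the group. In the other direction ANO5 went from 15 to 605 counts, a ratio of 41.3 (24.8 to 74.3), and KIAA1217 from 42 to 1001, a ratio of 24.4 (17.9 to 34.1). These genes were chosen after their values were seen, and the labels do not say whether the knockout libraries come from a single clone.

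Genes of chromosomes 7, 14, 16 and 21 were lower and those of chromosomes 10 and 13 higher in the knockout libraries. Bias from GC content or gene length is argued against, since the median of chromosome 21 stayed at -0.419 with that trend removed (-0.40 before). Differences between libraries of a group are argued against as well, with medians of chromosome 21 of at most 0.023 in size between them. A different copy number of these chromosomes, or of parts of them, in the knockout cells may be the source but was not tested. The 83.1% of tested chromosome 21 genes with a negative log2 fold change restates the shift that prompted the question. A different copy number stays open as a hypothesis, since no DNA was measured. The labels also do not say how the knockout cells were derived beyond the editing.

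Mitochondrially encoded RNAs were higher in the knockout libraries. None of 4 other scalings between libraries removed the rise, and the lowest median of the list over them was 0.679 (0.745 with TMM). These scalings lie close to TMM, with total counts at a median of all genes of -0.065. They could not have removed a rise of this size, so by themselves they decide nothing. The mitochondrial share of counts uses no scaling between libraries. It was 6.07% and 5.87% in the wild-type libraries and 8.61% and 10.16% in the knockout libraries. This argues against scaling as the source of the rise relative to nuclear genes, and leaves amounts per cell undecided. The median of the list was 0.567 on the TPM scale, which moves the median of all genes by -0.16, and quantile normalization fixes the outcome by construction. A bias of GC content or gene length is argued against by a median of 0.716 with the trend of nuclear genes removed. RNA quality and the state of the cultures were not measured and stay open beside an effect of the edit, which may change these transcripts but was not tested apart from them.

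The other 11 gene lists past camera could have followed shifts of whole chromosome regions. With the local median removed 9 of the 11 lists stayed past the threshold in the same direction, which argues against regional shifts as the whole cause for these. Calls ended for the heat shock genes, whose median went from 0.23 (SD 0.355) to 0.17 (SD 0.365, camera adjusted p = 0.0633). They also ended for the histone genes, from -0.47 (SD 0.491) to -0.33 (SD 0.507, camera adjusted p = 0.0669). Each list had a smaller median at a similar spread. Neighbours on the same list were not left out of the local median, so a lost call cannot show that a regional shift was the cause. With the GC and length trend removed 10 of the 11 stayed, all but the histone genes (-0.36, SD 0.488, adjusted p = 0.135). An effect of TTC28, of a clone or culture, or of the editing itself stays open for the 9 lists, since the labels do not say which of these the knockout libraries share.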
